A study of Mus musculus with 12 samples.

How the data were processed

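Total RNA of BW5147 cells was measured on 12 Affymetrix arrays, 2 in each of 6 groups, per the labels. The deposited values were signal intensity values of the MAS5 algorithm, per the submitters' processing notes, on a linear scale and in 2 tables, 1 with 11 arrays and the other with 1. In both tables the mean signal of each array after trimming 2% at each end was 100 (100.1 in 1 array), which shows a common scaling of the deposited intensities. The version of MAS5 and any further step are not given in the sources used here. Such scaling sets the mean level equal in all arrays, so a change of all genes in 1 direction could not be seen. No value column was left without a sample.

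The tables held the same probe sets. After removal of 64 control probe sets, 22626 remained, and signals were transformed as log2(signal + 16). Folds of low signals are understated on this scale. Probe sets with a mean log2 value above the 40th percentile were kept, 13575 in all, which corresponds to a signal of 6.32. Of all probe sets 20393 had 1 gene symbol in the platform annotation, 691 several and 1606 none. Gene identifiers of 20364 matched the gene table of the mouse assembly GRCm38.p6, used only for names, which changed 0 symbols. Genes were named only from probe sets with 1 symbol, by the probe set with the highest mean, which gave 7507 genes. No coordinates were used, because the arrays name no genome build.

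The test was a linear model in limma 3.58.1 (R 4.3.3) with 1 mean per group over the 11 arrays of the larger table, empirical Bayes moderation with an intensity trend, and Benjamini-Hochberg adjustment over all kept probe sets with a threshold of 0.05. There were 5 residual and 6.47 prior degrees of freedom. The groups shared 1 estimate of the spread because 2 arrays estimate it poorly. The array CCL1 2 was left out of this model since its table was made separately, and CCL1 alone therefore rested on 1 array whose spread was taken from the other groups. The 11 contrasts were each treatment against its control, the interactions with Dex and averages over conditions. Gene lists, 23 in number, were tested with camera at a preset inter-gene correlation of 0.01 on 1 probe set per gene, with adjustment over the lists of a comparison, and again with an estimated correlation and with fry.

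The genes named in each comparison followed a rule. These were the 10 largest rises and 10 largest falls among genes past the threshold whose arrays did not overlap between the groups, or, for averages, whose averaged differences shared a direction. Members of the gene lists past the threshold and up to 4 others per list were named, as were the receptor genes Nr3c1, Il9r and Ccr8. Where fewer than 5 genes passed, the 5 with the smallest p were named. Genes past the threshold with and without Dex were also named. The model with Dex split by replicate number was added later, and the rule was then applied to it. The signals per array of Il10, Nr4a1, Tnfsf14 and Dusp1 in that model were chosen after their values were seen. The rule itself, the contrasts, the lists and most alternatives were fixed before the data were examined.

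The alternatives were pseudocounts of 1 and 64, no filter and a filter at the 60th percentile, quantile normalization, median centring, no intensity trend, the replicate number as a block, the array CCL1 2 added, each array left out, a log2 change of at least 1 and 1 probe set per gene. The model with Dex split by replicate number, which has 5 residual degrees of freedom, the fits of the arrays of 1 number alone and the list tests with 1 array left out were added after the data were seen. Other splits of the arrays were fitted as 2 groups without further terms, at most 100 per comparison.

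The fits were tested on simulated data with the means and spreads of the 13575 probe sets and 200 changed ones. Values were drawn once, independently for each probe set and array. Beyond the changes put in, they held no correlation between genes, no difference by replicate number and no array standing apart like Dex 2. The shares below therefore do not show recovery in data with such features. For IL-9 versus unstimulated, 64.0% of changes of 1 log2 and 98.0% of changes of 2 log2 were recovered, with 2.99% false calls. For CCL1 versus unstimulated the shares were 34.0% and 99.0%, and for Dex versus unstimulated 76.0% and 100.0%, with 8.81% false calls. For Dex within the arrays numbered 2 they were 65.0% and 100.0%, and for the difference between numbers 39.0% and 100.0%, with 11.5% false calls. In a simulated list test on 7507 genes for CCL1 averaged over Dex conditions, the 1 shifted list was called, and 1 of 20 unshifted lists. Replicate arrays shared no set of identical values: the median absolute difference within a group was 0.168 to 0.258 log2.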

Results

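Gene expression was measured in BW5147 cells, a mouse thymic T lymphoma line, after 8 h of treatment. The line was left unstimulated or was given dexamethasone (Dex, a synthetic glucocorticoid, 100 ng/ml), interleukin-9 (IL-9, a T cell cytokine, 100 U/ml), the chemokine CCL1 (a ligand of the receptor Ccr8, 100 U/ml), Dex with IL-9, or Dex with CCL1. Each of the 6 groups held 2 arrays, 12 in all. The labels number the arrays of a group 1 and 2 and do not say whether they came from separate cultures. P-values of the model with 1 mean per group therefore measure the spread between these arrays, which may be technical. The number of arrays limits the precision. The array labelled CCL1 2 was measured on another array type and was left out of the tests unless it is named as added or all 12 arrays are named, so that CCL1 alone had n = 1 elsewhere. Changes are log2 differences of signal + 16 with their standard errors (SE), and adjusted p-values are from limma with Benjamini-Hochberg adjustment over 13575 probe sets.

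The effect of IL-9 was asked first in cells labelled without Dex. Of these, unstimulated 1 and IL-9 1 held glucocorticoid receptor targets at the level of the Dex arrays, as described below. Their centred mean levels were 0.167 and 0.199, against -0.413 and -0.319 in unstimulated 2 and IL-9 2. Bcl3, an atypical IkB protein of the NF-kB pathway, had a signal of 5.71 ± 0.528 (SD, n = 2) in unstimulated cells and 159 ± 1.06 (SD, n = 2) with IL-9, a rise of 3.01 log2 (SE 0.22, adjusted p = 0.000206). Gzma, encoding the cytotoxic granule protease granzyme A, rose by 2.31 (SE 0.20, adjusted p = 0.000619), from 23.8 ± 4.32 to 181 ± 15.4 (SD, n = 2 each). Sgk1, a serum- and glucocorticoid-regulated kinase, rose by 2.14 (SE 0.19, adjusted p = 0.000709), from 40.1 ± 9.93 to 230 ± 5.88 (SD, n = 2 each). These 3 probe sets passed the threshold and no probe set fell. Ccr9, a chemokine receptor of thymocytes and gut-homing T cells, had a difference of -1.67 (adjusted p = 0.0905) and Arid5a of 1.36 (adjusted p = 0.237), and neither passed. Among the receptor genes the difference was -0.41 (SE 0.22) for Il9r, -0.050 (SE 0.38) for Nr3c1, the glucocorticoid receptor, and -0.57 (SE 0.46) for Ccr8, none past the threshold. The fixed list of JAK-STAT and IL-9 response genes shifted up (16 measured members, 2 of them called over all probe sets and 6 adjusted over the list alone; camera adjusted p = 6.07e-08, and adjusted p = 0.0295 with an estimated correlation). Ribosome biogenesis and MYC targets shifted up with the preset correlation (20 measured, 0 called, 0 adjusted over the list alone; adjusted p = 0.00111) and not with an estimated one (adjusted p = 0.0865 with an estimated correlation). Both lists kept their shift at the preset correlation without any 1 of the 11 arrays. The JAK-STAT list lost it at an estimated one without any 1 array but CCL1 1 (adjusted p = 0.0545 to 0.126 with an estimated correlation). Bcl3, Gzma and Sgk1 kept their calls without any 1 of the 11 arrays, and the count was 5 without IL-9 replicate 2. Ccr9 passed without Dex replicate 1 or Dex replicate 2, with adjusted p from 0.0181 to 1 over all omitted arrays and from 0.0415 to 0.268 over the other settings.

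IL-9 was then compared within Dex-treated cells. The same 3 genes rose. Bcl3 rose by 2.70 (SE 0.22, adjusted p = 0.000461), Sgk1 by 2.32 (SE 0.19, adjusted p = 0.000461) and Gzma by 1.66 (SE 0.20, adjusted p = 0.0124). Signals with Dex and IL-9 were 129 ± 20.6 for Bcl3, 276 ± 49.3 for Sgk1 and 136 ± 21.4 for Gzma, against 6.56 ± 5.58, 42.2 ± 4.03 and 31.6 ± 2.61 with Dex alone (SD, n = 2 each). All 3 calls were shared in direction with the comparison without Dex, whose arrays numbered 1 held glucocorticoid targets at the level of the Dex arrays. That comparison used other arrays for its means, but both shared 1 estimate of the spread, so their p-values are not independent. Ndrg3 (2.67, adjusted p = 0.0541) and Socs1 (1.36, adjusted p = 0.0959), a feedback inhibitor of JAK kinases, did not pass. The differences of Ccr8 (-0.56, SE 0.46), Nr3c1 (0.22, SE 0.38) and Il9r (-0.22, SE 0.22) did not pass. The JAK-STAT and IL-9 response list again shifted up (2 of 16 called, 6 adjusted over the list alone; camera adjusted p = 1.60e-08, adjusted p = 0.0251 with an estimated correlation). The anti-apoptotic list, which also holds Bcl3, shifted up with the preset correlation (10 measured, 1 called, also 1 adjusted over the list alone; adjusted p = 0.0431) and not with an estimated one (adjusted p = 0.248 with an estimated correlation). So did ribosome biogenesis and MYC targets (0 of 20 called, 0 adjusted over the list alone; adjusted p = 0.000295, adjusted p = 0.0630 with an estimated correlation). Signals in the Dex arrays 1 and 2 were 2500 and 1310 for Ncl and 542 and 258 for Nop58 of that list, and 267 and 380 for Bop1. The list kept its shift without Dex replicate 2 (adjusted p = 0.00132) and lost it without Dex+IL-9 replicate 1 (adjusted p = 0.0737). The anti-apoptotic list lost its shift without any 1 array but Dex 1 and CCL1 1 (adjusted p = 0.0502 to 0.175). The JAK-STAT list lost it at an estimated correlation without any 1 array but Dex 2 and CCL1 1 (adjusted p = 0.0563 to 0.308 with an estimated correlation). Gzma lost its call without Dex replicate 2 (adjusted p = 0.0833), Dex+IL-9 replicate 1 (adjusted p = 0.460) or Dex+IL-9 replicate 2 (adjusted p = 0.102). The count was 668 without Dex replicate 1, which left the array Dex 2 alone in its group, and 5 without IL-9 replicate 1, without IL-9 replicate 2 or with the array CCL1 2 added. Ndrg3 passed with a pseudocount of 64 (adjusted p = 0.0377), median centring (0.0247), the array CCL1 2 added (0.0268) and 1 probe set per gene (0.0249), and Socs1 with a pseudocount of 64 (0.0357). Over all settings other than an omitted array their adjusted p ranged from 0.0106 to 0.191 and from 0.0357 to 0.433. Ndrg3 passed without Dex replicate 1, IL-9 replicate 1 or IL-9 replicate 2 and Socs1 without Dex replicate 1, with adjusted p over all omitted arrays from 0.00101 to 0.691 and from 0.00450 to 0.878.

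Averaged over the conditions with and without Dex, IL-9 raised 9 probe sets of 8 genes and lowered 4 probe sets, 2 genes among them. The rises were Bcl3 (2.85, SE 0.15, adjusted p = 8.10e-06), Ndrg3 (2.42), Sgk1 (2.23), Gzma (1.99), Arid5a (1.36), Socs1 (1.17, SE 0.15, adjusted p = 0.0103), Stat3 (0.96, SE 0.13, adjusted p = 0.0124), a transcription factor activated by JAK kinases, and Ptger4 (0.82), a prostaglandin E receptor. The falls were Ccr9 (-1.59, SE 0.18, adjusted p = 0.00401), from 258 ± 6.36 in unstimulated cells to 71.1 ± 19.1 with IL-9 (SD, n = 2 each), and Wdr6 (-0.64, adjusted p = 0.0231). The differences of Ccr8 (-0.57), Nr3c1 (0.085) and Il9r (-0.32) did not pass. In the JAK-STAT and IL-9 response list, Bcl3, Gzma, Socs1 and Stat3 were called, 6 of 16 members passed adjusted over the list alone, and the list shifted up (camera adjusted p = 2.53e-09, adjusted p = 0.0204 with an estimated correlation). Junb (0.82, adjusted p = 0.200), Bcl6 (0.61, adjusted p = 0.256), Cish (0.091) and Pim1 (0.18) of that list did not pass. The list of ribosome biogenesis and MYC targets shifted up with no single member called, also when adjusted over the list alone: 19 of 20 differences were positive with a median of 0.21, such as Bop1 at 0.34 (camera adjusted p = 9.28e-06, adjusted p = 0.0318 with an estimated correlation). The centred mean level of this list was lowest in Dex 2, at -0.205, against -0.123 in Dex 1 and -0.0901 and -0.0872 in the unstimulated arrays, and lay between -0.00833 and 0.101 in the others. Ncl had a signal of 2500 in Dex 1 and 1310 in Dex 2. Without Dex replicate 2, 16 members were positive (adjusted p = 4.03e-05, adjusted p = 0.0763 with an estimated correlation). At the preset correlation the shift held without any 1 array, and at an estimated one it was lost without any 1 but CCL1 1 (adjusted p = 0.0524 to 0.111 with an estimated correlation). The JAK-STAT list lost its shift at an estimated correlation without any 1 of unstimulated 1, Dex 1, Dex+IL-9 1, Dex+CCL1 2, IL-9 1 and IL-9 2 (adjusted p = 0.0512 to 0.0984 with an estimated correlation). The count of 13 probe sets was 358 without Dex replicate 1, 21 without Dex replicate 2, 8 without unstimulated replicate 1 or Dex+IL-9 replicate 2, and 5 without Dex+IL-9 replicate 1. Calls were lost by Arid5a without Dex+IL-9 replicate 1 (adjusted p = 0.0727) and by Socs1 without any 1 of unstimulated 1, IL-9 1, Dex+IL-9 1 and Dex+IL-9 2 (up to 0.0958). Ptger4 lost its call without any 1 of these or unstimulated 2 (up to 0.0951). Stat3 lost its call without any 1 array of the unstimulated, IL-9 and Dex+IL-9 groups (up to 0.116), and Wdr6 without any 1 of those or of the Dex+CCL1 arrays (up to 0.214). Socs1 also lost its call with a pseudocount of 1 (adjusted p = 0.0764) and Wdr6 with median centring (0.0623) and without the intensity trend (0.0753). Over all other settings their adjusted p ranged from 0.00418 to 0.771 and from 0.00416 to 0.771. Bcl3, Ndrg3, Sgk1, Gzma and Ccr9 kept their calls without any 1 of the 11 arrays. In the arrays numbered 2 alone, with all 12 arrays available, Ndrg3, Gzma and Ccr9 did not pass by limma (adjusted p = 0.16, 0.135 and 0.152). Arid5a, Stat3 and Ptger4 did not pass there either (0.135, 0.392 and 0.771). The differences there kept the direction of the average: 2.09 for Ndrg3, 1.93 for Gzma, -1.31 for Ccr9, 1.33 for Arid5a, 0.908 for Stat3 and 0.768 for Ptger4. In that fit each treatment held 1 array, so a lost call does not show a lost change. Bcl3 and Sgk1 kept their calls over the other settings (adjusted p up to 0.0225 for each).

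**Figure D1:**
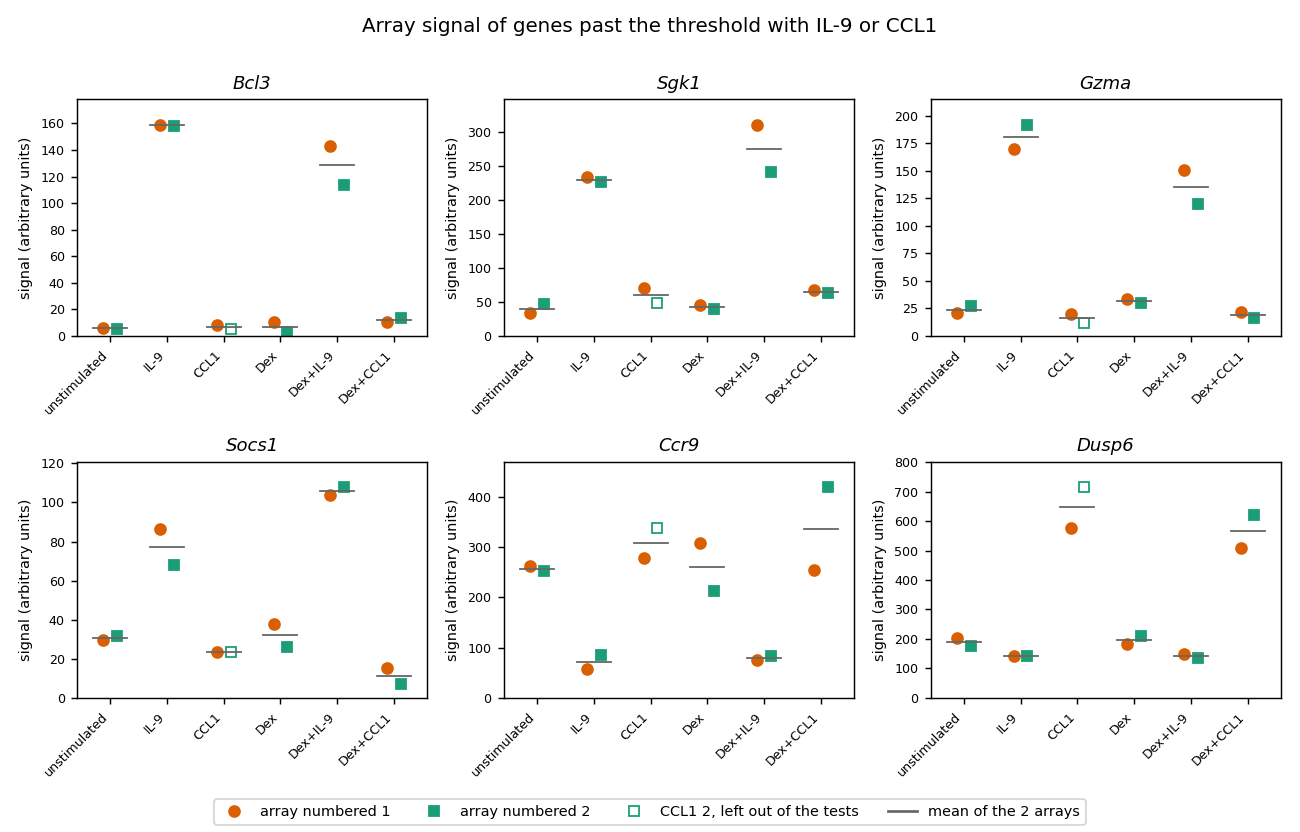
Array signal (arbitrary units, linear axis from 0) of Bcl3, Sgk1, Gzma, Socs1, Ccr9 and Dusp6 in the 6 groups; each point is 1 array, circles for arrays numbered 1 and squares for arrays numbered 2, the open square is the array CCL1 2, and the line is the mean of the 2 arrays. Bcl3 lay at 114 or above in the 4 arrays with IL-9 and at 13.3 or below in the others, and Dusp6 lay at 509 or above in the 4 arrays with CCL1 and at 209 or below in the others.

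CCL1 was compared with the unstimulated cells and, within Dex-treated cells, with Dex alone. The tested CCL1 array was numbered 1 and the unstimulated mean held both numbers, so the comparison without Dex carries part of the difference between numbers. Without Dex that difference was called in 108 probe sets by limma in the later model with Dex split by number. Dusp6, a phosphatase that inactivates ERK kinases and is itself an ERK target, had a signal of 578 in the tested CCL1 array and 189 ± 20.5 (SD, n = 2) in unstimulated cells. Its difference of 1.54 (SE 0.20) had the smallest p without Dex and missed the threshold (adjusted p = 0.0932). No probe set passed in that comparison by limma, with 446 at an unadjusted p under 0.05 where 679 would arise by chance. Ube2d2a (-0.72), Pglyrp2 (1.32), Pcm1 (-1.15) and Tuba8 (1.21) had the next smallest p and did not pass, and Ccr8 (1.16, SE 0.56), Nr3c1 (0.54) and Il9r (-0.51) did not either. Dusp6 passed with a pseudocount of 64 (adjusted p = 0.0492), with 1 probe set per gene (adjusted p = 0.0410), with the array CCL1 2 added (1.69, adjusted p = 0.00260), without Dex replicate 1 (adjusted p = 0.0301) and without Dex replicate 2 (adjusted p = 0.0321). Its adjusted p ranged from 0.00260 to 0.262 over the other settings and from 0.0301 to 0.486 over the omitted arrays. Within Dex-treated cells, Dusp6 was the only probe set past the threshold, rising by 1.45 (SE 0.16, adjusted p = 0.0222) from 196 ± 17.9 to 565 ± 79.6 (SD, n = 2 each). Id2, an inhibitor of basic helix-loop-helix transcription factors (1.24, adjusted p = 0.180), Tuba8 (1.52, adjusted p = 0.348), Sytl2 (1.24) and Abat (1.38) did not pass there, nor did Ccr8 (0.45), Nr3c1 (0.20) and Il9r (-0.31). The call for Dusp6 within Dex was lost without the intensity trend (adjusted p = 0.0688) and without 1 array of the unstimulated, IL-9, Dex+IL-9 or Dex+CCL1 groups, where no probe set was called. Its adjusted p there ranged from 0.0547 without unstimulated replicate 2 to 0.847 without Dex+CCL1 replicate 2. Over the other settings it ranged from 0.00950 to 0.0688. Without Dex replicate 1 the count was 528, and Id2, Tuba8, Sytl2 and Abat were among those that passed (adjusted p = 0.00749, 0.00953, 0.00837 and 0.0233).

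Averaged over the Dex conditions, CCL1 raised Dusp6 (1.50, SE 0.13, adjusted p = 0.00141) and no other probe set. Tuba8 (1.37, adjusted p = 0.162), Pglyrp2 (1.34, adjusted p = 0.181), Abat (1.31, adjusted p = 0.181) and Usp18 (1.00, adjusted p = 0.25) followed and did not pass. The values of Ccr8 (0.80, SE 0.36), Nr3c1 (0.37) and Il9r (-0.41) did not pass. This average also carries part of the difference between numbers. In the arrays numbered 1 alone, with all 12 arrays available, the difference of Ccr8 was 0.489. The MAPK immediate-early and feedback list, which holds Dusp6, shifted up with the preset correlation (12 measured, 1 called, 2 adjusted over the list alone; adjusted p = 0.000132) and not with an estimated one (adjusted p = 0.0611 with an estimated correlation). It did so as well in CCL1 versus unstimulated (adjusted p = 0.0181, and adjusted p = 0.198 with an estimated correlation). Within Dex it did too (adjusted p = 0.00106, and adjusted p = 0.0983 with an estimated correlation), with 2 members in each adjusted over the list alone. Other members had Nr4a1 at 1.40 (adjusted p = 0.361), Egr3 at 0.30, Etv5 at 0.30 and Fos at 0.19. All 20 members of the ribosome biogenesis and MYC list had positive differences with a median of 0.20, none called and none adjusted over the list alone, as for Nolc1 at 0.38 and Ddx21 at 0.40 (adjusted p = 1.64e-05, and adjusted p = 0.0611 with an estimated correlation). In CCL1 versus unstimulated 17 were positive (adjusted p = 0.0181, adjusted p = 0.198 with an estimated correlation) and within Dex 18 were (adjusted p = 0.000322, adjusted p = 0.0983 with an estimated correlation), none called and none adjusted over the list alone. The centred mean level of this list was -0.205 in Dex 2 and -0.123 in Dex 1, with Ncl at 1310 and 2500. Without Dex replicate 2, 17 members were positive in the average (adjusted p = 6.21e-05, adjusted p = 0.0941 with an estimated correlation) and 17 within Dex (adjusted p = 0.000578, adjusted p = 0.139 with an estimated correlation). At the preset correlation the shift held in these 3 comparisons without any 1 array that could be left out. The MAPK list lost its shift within Dex without Dex replicate 1 (adjusted p = 0.0973). The IL-9 and CCL1 averages used the same unstimulated and Dex arrays, so part of their shared direction in this list may come from those arrays. Cholesterol synthesis genes (15 measured) and heat shock proteins (9 measured) shifted up with the preset correlation (adjusted p = 0.0122 and 0.0133), with no member called or passing adjusted over the list alone, and not with an estimated one (adjusted p = 0.816 and 0.483 with an estimated correlation). The cholesterol list lost its shift without unstimulated replicate 1, Dex replicate 1 or Dex+CCL1 replicate 2 (adjusted p = 0.522, 0.224 and 0.291). Heat shock proteins lost theirs without unstimulated replicate 2, Dex replicate 2 or Dex+CCL1 replicate 2 (adjusted p = 0.122, 0.123 and 0.189). The call of Dusp6 held without any 1 of 10 arrays. It was lost in the arrays numbered 2 alone, with all 12 arrays available (1.72, adjusted p = 0.0571 by limma). The count of 1 became 66 without Dex replicate 1, 3 without unstimulated replicate 2 and 3 with the array CCL1 2 added. Tuba8 and Abat passed in each of these (adjusted p down to 0.0196 and 0.0297 with 1 array left out), and Pglyrp2 and Usp18 without Dex replicate 1 (0.0367 and 0.0308).

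The IL-9 and CCL1 conditions were also set against each other, averaged over Dex. With IL-9, 12 probe sets were higher and 20 lower than with CCL1. Of the 23 genes called by their probe set with the highest mean, 9 had 18 other tested probe sets. Only 16 of these had the same direction. Higher with IL-9 were Bcl3 (2.61, SE 0.17, adjusted p = 3.88e-05), Ndrg3 (2.43), Gzma (2.27), Socs1 (1.71), Sgk1 (1.67), Ptger4 (1.47, SE 0.12, adjusted p = 0.000166), the threonine aldolase gene Tha1 (1.36), Zfp36 (1.00), which encodes an mRNA decay factor, and Stat3 (0.99). Lower with IL-9 were Dusp6 (-1.90, SE 0.13, adjusted p = 3.88e-05), Ccr9 (-1.81), Tuba8 (-1.61), Sytl2 (-1.41), Abat (-1.32), Pglyrp2 (-1.22), Pde7a (-1.22), St3gal2 (-1.21, SE 0.14, adjusted p = 0.00414), Mpp4 (-0.93) and Prkd2 (-0.92). Ccr8 (-1.37, SE 0.36, adjusted p = 0.312), Nr3c1 (-0.29) and Il9r (0.094) did not pass. CCL1 without Dex rested on an array numbered 1, so part of the difference between numbers enters here as well. With all 12 arrays available, Ccr8 had -0.886 in the arrays numbered 1 alone and -1.24 in those numbered 2 alone. The JAK-STAT and IL-9 response list lay higher with IL-9 (4 of 16 called, 7 adjusted over the list alone; adjusted p = 9.45e-17, adjusted p = 0.00504 with an estimated correlation). The anti-apoptotic list also did with the preset correlation (1 of 10 called, 1 adjusted over the list alone; adjusted p = 0.0151, adjusted p = 0.219 with an estimated correlation). Cholesterol synthesis genes lay lower with IL-9 (none called, none adjusted over the list alone; adjusted p = 0.0210, adjusted p = 0.573 with an estimated correlation). The anti-apoptotic list did not pass without Dex+CCL1 replicate 2 or IL-9 replicate 1 (adjusted p = 0.0534 and 0.0552). The cholesterol list did not without Dex+IL-9 replicate 1, Dex+CCL1 replicate 2 or IL-9 replicate 1 (adjusted p = 0.223, 0.334 and 0.288). The total of 32 probe sets was 51 and 52 without Dex replicates 1 and 2, and 14 without Dex+IL-9 replicate 1, Dex+IL-9 replicate 2 or Dex+CCL1 replicate 1. It was 16 without Dex+CCL1 replicate 2 or IL-9 replicate 1, and 19 without IL-9 replicate 2. Bcl3, Ndrg3, Gzma, Socs1, Sgk1, Ptger4, Dusp6, Ccr9, Tuba8 and St3gal2 kept their calls without any 1 of 10 arrays. Of the others, Tha1, Zfp36, Pglyrp2 and Mpp4 lost theirs without any 1 array of the unstimulated, IL-9, Dex+IL-9 or Dex+CCL1 groups (adjusted p up to 0.203, 0.251, 0.251 and 0.231). Abat and Prkd2 did so without any 1 of those outside the unstimulated group (up to 0.137 and 0.249). Stat3 lost its call without IL-9 1, IL-9 2, Dex+IL-9 1, Dex+IL-9 2 or Dex+CCL1 1 (up to 0.112). Pde7a lost its call without IL-9 2, Dex+IL-9 2, Dex+CCL1 1 or Dex+CCL1 2 (up to 0.0827) and Sytl2 without Dex+IL-9 1, Dex+IL-9 2 or Dex+CCL1 1 (up to 0.0655). With a pseudocount of 1 and with no filter Tha1, Zfp36, Abat, Pglyrp2, Mpp4 and Prkd2 did not pass. Over all other settings their adjusted p reached 0.864, 0.360, 0.807, 0.864, 0.515 and 0.787. In the arrays numbered 2 alone, with all 12 arrays available, Ndrg3, Socs1 and St3gal2 did not pass by limma (adjusted p = 0.0965, 0.261 and 0.432). Stat3, Sytl2 and Pde7a did not pass there either (0.238, 0.515 and 0.432). The differences there kept their direction: 2.13 for Ndrg3, 1.76 for Socs1, -0.922 for St3gal2, 0.905 for Stat3, -1.13 for Sytl2 and -1.07 for Pde7a. In that fit each treatment held 1 array, so a lost call does not show a lost difference.

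Dex was compared with no Dex to find the glucocorticoid response. Tsc22d3, encoding the glucocorticoid-induced leucine zipper, had a signal of 347 and 109 in the arrays labelled unstimulated 1 and 2 and of 349 and 422 in the Dex arrays, a difference of 0.91 (SE 0.50, adjusted p = 0.995). Fkbp5, a co-chaperone of the glucocorticoid receptor, had 767 and 306 without and 611 and 688 with Dex (0.41, SE 0.35). No probe set passed in Dex versus unstimulated by limma, with 400 at an unadjusted p under 0.05 where 679 would arise by chance, and none passed for Dex averaged over the cytokine conditions, with 208. The smallest p without cytokine belonged to Pcm1 (-1.06), Ddr2 (-0.84), Cysrt1 (-1.02), Cpeb4 (-1.02) and Atp13a3 (-0.96), and in the average to Plcg2 (0.53), Arhgef25 (-0.52), Slc34a1 (0.42), Vipas39 (0.34) and Spry4 (-0.45); none of these passed. Ccr8 (0.71, SE 0.46), Nr3c1 (0.0385) and Il9r (0.25) did not pass without cytokine, nor did Ccr8 (0.47), Nr3c1 (0.015) and Il9r (0.38) in the average. Of 16 measured members of the glucocorticoid receptor target list none was called, also when adjusted over the list alone, and 13 had positive differences without cytokine. The list shifted up with the preset correlation in Dex versus unstimulated (adjusted p = 0.00764) and in the average (adjusted p = 0.000558), but not with an estimated one (adjusted p = 0.685 and 0.595 with an estimated correlation). It lost the first shift without unstimulated replicate 2, Dex replicate 1 or Dex replicate 2 (adjusted p = 0.833, 0.0563 and 0.151). It lost the second without unstimulated replicate 2 or IL-9 replicate 2 (adjusted p = 0.0545 and 0.148). The centred mean level of the list was 0.167 in the array labelled unstimulated 1 and -0.413 in unstimulated 2, against 0.088 in Dex 1 and 0.281 in Dex 2, and directions are those of the labels. Without Dex replicate 1, Dex versus unstimulated gave 529 probe sets, 527 of them lower with Dex, from the array Dex 2 alone, in which 426 probe sets lay over 1 log2 from the mean of the other arrays, with Pcm1, Ddr2, Cpeb4 and Atp13a3 among them (adjusted p = 0.00426, 0.0107, 0.0179 and 0.00468).

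The replicate number of the labels was examined as a possible batch. Arrays were split by it after the values had been seen, in a model with a mean for Dex and no Dex within each number and additive IL-9 and CCL1 terms. Each treatment held at most 1 array per number, so p-values of this model measure departures from additive cytokine effects. These include differences of a cytokine effect between the numbers, and so part of the spread between arrays of 1 treatment. A spread between arrays of the same treatment and number could not be measured. Without Dex the tested arrays numbered 2 were unstimulated 2 and IL-9 2, set against Dex 2, Dex+IL-9 2 and Dex+CCL1 2. Among the arrays numbered 2, Dex raised 69 probe sets and lowered 12. The largest rises were Akap12, a kinase anchoring protein (2.56, SE 0.16, adjusted p = 1.57e-05), Ggct (2.51), Tsc22d3 (1.79, SE 0.14, adjusted p = 6.15e-05), Tnfsf14 (1.77), Bcl2l11, encoding the pro-apoptotic protein Bim (1.74, SE 0.17, adjusted p = 0.000357), Zfp36l2 (1.62), Ccr8 (1.48, SE 0.13, adjusted p = 0.000159), Tnfrsf18, encoding the costimulatory receptor GITR (1.46), Irf8 (1.42) and Stat4 (1.37). The falls were led by Stc1 (-1.45), Nr1d1, a repressor of the circadian clock (-1.14), Plekha3 (-0.89), Slc25a24 (-0.73) and Dipk2a (-0.72). In the glucocorticoid receptor target list, 7 of 16 members were called up and none down, Tsc22d3, Dusp1 (1.34), Per1 (1.07), Fkbp5 (1.03), Klf13 (1.03), Nfkbia (0.90) and Ddit4 (0.88). Adjusted over the list alone 10 rose and 1 fell (camera adjusted p = 1.85e-11, adjusted p = 0.0254 with an estimated correlation). The estimated one was lost without any 1 array but Dex 2, Dex+IL-9 2 and IL-9 1 (adjusted p = 0.0524 to 0.189 with an estimated correlation). Of 11 measured pro-apoptotic genes, Bcl2l11 and Gpr65 (1.35, adjusted p = 0.0240), a proton-sensing receptor, were called, also 2 adjusted over the list alone, and the list test did not pass (adjusted p = 0.207). Nr3c1 (0.24) and Il9r (0.42) did not pass. The count of 81 was 29 without unstimulated replicate 2, 31 and 45 without IL-9 replicates 2 and 1, and 41 without Dex+IL-9 replicate 1. It was 46 and 49 without Dex+CCL1 replicates 1 and 2 and 50 without Dex replicate 1, and 44 with no filter. Without Dex+IL-9 replicate 2 it was 117, with 66 of them lower. The array Dex 2, part of this comparison, stood apart, with 426 probe sets over 1 log2 from the mean of the other arrays. Without it, Nr1d1, Plekha3 and Ddit4 were the named genes that lost their calls. Akap12, Ggct, Tsc22d3, Tnfsf14, Bcl2l11, Zfp36l2, Ccr8, Tnfrsf18, Stat4 and Dusp1 kept their calls without any 1 of the 11 arrays. Calls were lost by Fkbp5 without unstimulated 2 (adjusted p = 0.0983), Irf8 without unstimulated 2 or IL-9 2 (up to 0.0765), and Nfkbia and Stc1 without IL-9 2 (0.140 and 0.219). Per1, Klf13, Ddit4, Gpr65, Nr1d1, Plekha3, Slc25a24 and Dipk2a lost theirs without any 1 of several arrays (up to 0.424, 0.403, 0.471, 0.337, 0.403, 0.486, 0.389 and 0.295). Their calls were lost under at least 1 other setting too (up to 0.0997, 0.113, 0.0669, 0.0578, 0.135, 0.105, 0.111 and 0.0626). These arrays were all but Dex+IL-9 1 for Nr1d1, all but Dex 2 for Slc25a24, and all but unstimulated 1 and Dex+IL-9 2 for Plekha3. They were all but unstimulated 1, Dex 2 and CCL1 1 for Per1, and all but those and Dex+IL-9 2 for Klf13 and Dipk2a. For Gpr65 they were all but unstimulated 1, the Dex arrays and CCL1 1. For Ddit4 they were unstimulated 2, both Dex arrays, both Dex+IL-9 arrays and Dex+CCL1 1.

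Among the arrays numbered 1, no probe set passed for Dex by limma, with 339 at an unadjusted p under 0.05 where 679 would arise by chance. Golt1b (-0.59), Reep5 (-0.45), Clec16a (-0.72), Rasgrp1 (0.57) and Ccnt1 (-0.46) had the smallest p and did not pass, and neither did Ccr8 (-0.049, SE 0.11), Nr3c1 (0.044) or Il9r (0.31). The glucocorticoid receptor target list had no member called, none adjusted over the list alone and a median of -0.030 there (adjusted p = 0.674). The difference of the Dex effect between the numbers was tested itself: 27 probe sets had a larger Dex effect in the arrays numbered 2 and 1 a smaller one, with Akap12 (2.78), Ggct (2.48), Bcl2l11 (2.00), Zfp36l2 (1.85), Tsc22d3 (1.81), Tnfsf14 (1.79), Tnfrsf18 (1.75), Dusp1 (1.59), Irf8 (1.59) and Ccr8 (1.53, SE 0.17, adjusted p = 0.00181) leading. In the glucocorticoid receptor target list, 4 of 16 had a larger effect, Tsc22d3, Dusp1, Nfkbia and Fkbp5 (10 larger and 1 smaller adjusted over the list alone; adjusted p = 6.19e-09, adjusted p = 0.0450 with an estimated correlation). The estimated one was lost whichever of the 11 arrays was left out (adjusted p = 0.0662 to 0.311 with an estimated correlation). Fkbp5 lost its call without any 1 of unstimulated 1, unstimulated 2, Dex 1, Dex+IL-9 1, Dex+CCL1 1, IL-9 2 and CCL1 1 (adjusted p up to 0.165). It also did without the intensity trend (0.0787, with 0.00538 to 0.0787 over the other settings). Nfkbia lost its call without IL-9 1 or IL-9 2 (0.0689 and 0.108). Without Dex, Dusp1 had a signal of 228 in the array unstimulated 1 and of 62.9 in unstimulated 2, and Akap12 244 and 16.8. This count of 28 was 15 to 44 when 1 array was left out, lowest without Dex+CCL1 replicate 1 or IL-9 replicate 1 and highest without Dex+IL-9 replicate 2, and 16 without unstimulated replicate 2. Calls were lost by Tnfsf14 and Tnfrsf18 without unstimulated 2 (adjusted p = 0.0553 and 0.0575), by Tnfrsf18 without Dex+CCL1 1 (0.0637), and by Irf8 without any 1 array other than Dex 2, Dex+IL-9 1 and Dex+IL-9 2 (up to 0.147). Under other settings the same 3 calls were lost at least once (adjusted p up to 0.103, 0.0726 and 0.0800), and Akap12, Ggct, Bcl2l11, Zfp36l2, Tsc22d3, Dusp1 and Ccr8 kept theirs throughout.

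**Figure D2:**
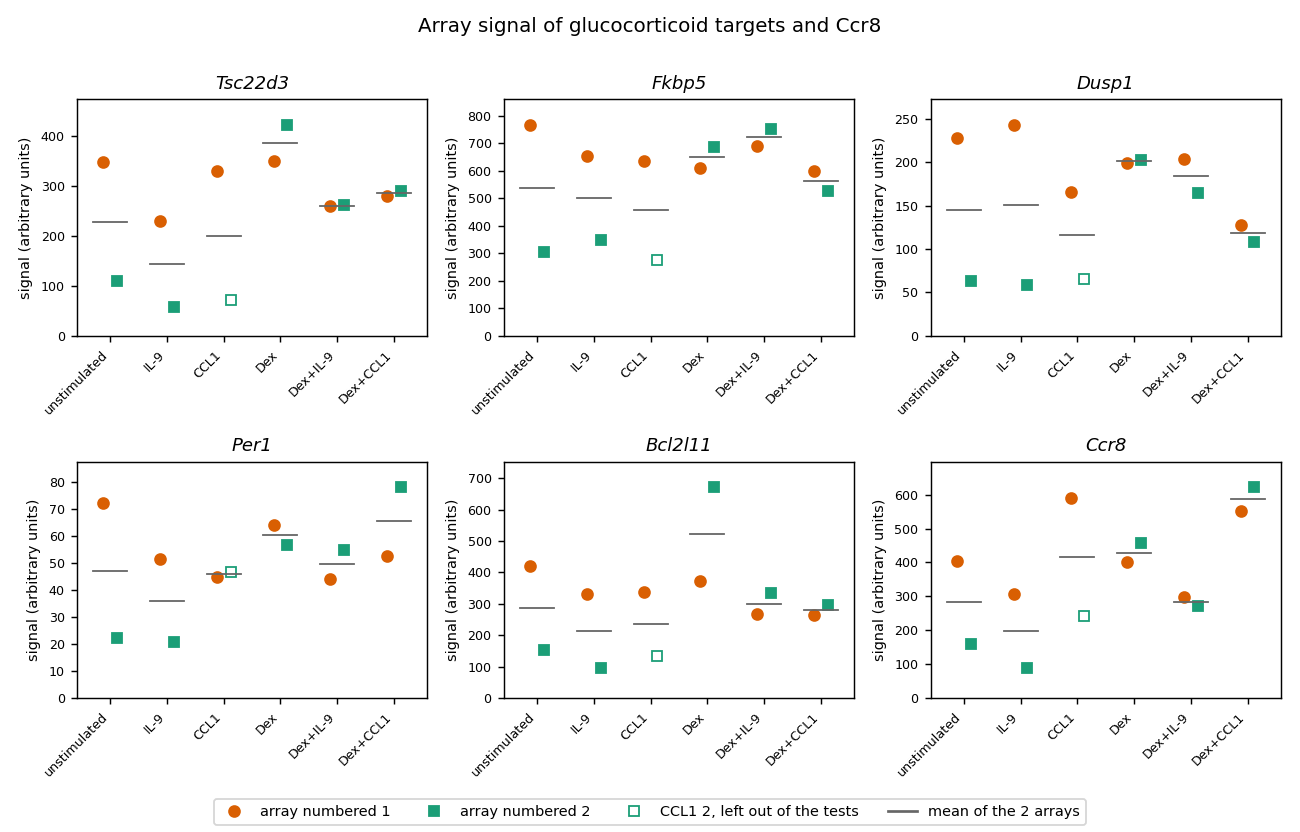
Array signal (arbitrary units, linear axis from 0) of Tsc22d3, Fkbp5, Dusp1, Per1, Bcl2l11 and Ccr8 in the 6 groups; each point is 1 array, circles for arrays numbered 1 and squares for arrays numbered 2, the open square is the array CCL1 2, and the line is the mean of the 2 arrays. Tsc22d3 lay at 109, 58.7 and 70.8 in the 3 arrays numbered 2 without Dex and between 230 and 422 in the others.

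Whether Dex altered the response to either cytokine was tested as an interaction. Cysrt1 (2.25, SE 0.43, adjusted p = 0.997), Clcn5 (1.68), Pcm1 (1.51), Armcx2 (1.47) and Cpox (1.70) had the smallest p for CCL1, and Tspan9 (1.11), Pcm1 (1.30), 1810058I24Rik (-1.02), Adcyap1r1 (-0.90) and Nxph3 (-0.89) for IL-9. None of them passed. By limma no probe set was called in either interaction. At an unadjusted p under 0.05 there were 390 for CCL1 and 215 for IL-9, where 679 would arise by chance. With the array levels given below, the absence of calls does not show that Dex left either response unchanged. The interactions of Ccr8 (0.013 for IL-9 and -0.71 for CCL1), Nr3c1 (0.27 and -0.34) and Il9r (0.19 and 0.20) did not pass. The arrays without Dex included unstimulated 1, IL-9 1 and CCL1 1, where the centred mean level of the glucocorticoid receptor targets was 0.167, 0.199 and 0.019 against 0.0278 to 0.281 in the Dex arrays, and CCL1 alone rested on CCL1 1. Without Dex replicate 1 the counts were 271 for IL-9 and 101 for CCL1, with Pcm1 (adjusted p = 0.0162 and 0.0266), Cysrt1 (0.0448) and Clcn5 (0.0337) among them.

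In the model with Dex split by number, chosen after the values had been seen, the cytokine averages held more calls. Their p-values again measured departures from additive cytokine effects. IL-9 raised 43 probe sets and lowered 68, including all 13 called before, and among the added genes Il10 (1.45, SE 0.24, adjusted p = 0.0199), an anti-inflammatory cytokine, Pdcd1 (1.27), encoding the inhibitory receptor PD-1, Tha1 (1.27), Gadd45g (1.13), Fos (1.13), Junb (0.82) and Jak3 (0.77) rose. Bbip1 (-1.06), Mxd4 (-1.05), an antagonist of MYC, Tktl1 (-1.01), Ccng2 (-0.95), Dusp10 (-0.90), Ahsg (-0.855), Map2k6 (-0.82), Hsd17b11 (-0.78), Btg2 (-0.76), Pdgfrb (-0.67), Xbp1 (-0.45), Tsc22d3 (-0.59, SE 0.10, adjusted p = 0.0232) and Ccr8 (-0.57, SE 0.10, adjusted p = 0.0209) fell with IL-9. CCL1 raised 22 probe sets and lowered 22 there, with Tuba8 (1.52), Dusp6 (1.47), Abat (1.35), Pglyrp2 (1.29), Nr4a1 (1.20, SE 0.16, adjusted p = 0.0135), an orphan nuclear receptor induced early after T cell receptor signals, Usp18 (1.09), Sytl2 (1.04), Il17re (0.99), Pde7a (0.96) and Pacs2 (0.93) rising. Tnfsf14 (-1.12), Ahsg (-1.11), Tubb2a (-0.94), Hsd17b11 (-0.94), Zfp704 (-0.92), Smox (-0.91), Myzap (-0.85), Bbip1 (-0.81), Mxd4 (-0.81), Selenbp1 (-0.75) and Dusp1 (-0.61) fell with CCL1. Between the cytokines 46 probe sets were higher with IL-9 and 59 lower. Beside genes named before for that comparison, Il10 (1.89), Pdcd1 (1.49), Tnfsf14 (1.31), Junb (0.80), Socs2 (0.79), Mt1 (0.64) and Dusp1 (0.555) were higher with IL-9. Nr4a1 (-1.30), Pacs2 (-1.28), Ccr8 (-1.01), Usp18 (-0.955), Lcp2 (-0.90) and Lef1 (-0.67) were lower. Ccr8 had a difference of 0.44 with CCL1 (adjusted p = 0.119). It passed with the array CCL1 2 added to that model (0.495, adjusted p = 0.0341) and in the arrays numbered 1 alone with all 12 arrays available (0.489, adjusted p = 0.0483), with 0.0341 to 0.982 over all settings other than an omitted array. Nr3c1 and Il9r passed in none of the 3 comparisons of that model. Cholesterol synthesis genes shifted up with CCL1 in that model (none of 15 called, 5 adjusted over the list alone; adjusted p = 4.11e-06, adjusted p = 0.0345 with an estimated correlation). The MAPK and the ribosome biogenesis and MYC lists did too (adjusted p = 9.84e-06 for each, adjusted p = 0.0453 and 0.0345 with an estimated correlation). At the preset correlation these 3 shifts held without any 1 of the 11 arrays, and at an estimated one each was lost whichever array was left out (adjusted p = 0.0598 to 0.166 with an estimated correlation). Heat shock proteins also passed with CCL1 at the preset correlation, and did not without any 1 of several arrays (camera adjusted p up to 0.588). For IL-9 against CCL1 the same held for the T cell receptor and lineage list (up to 0.233). The anti-apoptotic list passed there too, but not without CCL1 1 (0.0625). Il10 had a signal of 117 in the array IL-9 1 and 5.91 in IL-9 2. Nr4a1 had a signal of 87.1 in CCL1 1 and 34.1 in unstimulated 1, and of 8.49 in CCL1 2, which was not in that fit, and 7.21 in unstimulated 2. In CCL1 2 and unstimulated 2, the signals were 11.9 and 11.8 for Tnfsf14 and 65.4 and 62.9 for Dusp1. In the arrays numbered 2 alone, with all 12 arrays available, IL-9 gave 2 probe sets and CCL1 none.

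Of the 23 gene lists, 21 had at least 2 measured members. In the 11 comparisons 7 of them passed the list test at least once and 14 in none, with a smallest adjusted p of 0.115 among the latter. The fibroblast and myeloid marker lists, for other cell types, were among those that passed in none. Of 4 measured fibroblast and stromal markers, Pdgfrb, a growth factor receptor, was lower adjusted over the list alone in IL-9 and in CCL1 averaged over Dex conditions. It was called with IL-9 in the model with Dex split by number (-0.67, SE 0.11, adjusted p = 0.0199). Its signal was 293 to 391 in the unstimulated and Dex arrays and 181 to 296 in the arrays with IL-9 or CCL1. The array Dex 2 stood apart from the other arrays: on the first principal component (24.0% of the variance) it lay at 39.5, the others between -12.2 and 10.2, and 426 of 13575 probe sets lay over 1 log2 from the mean of the other arrays, against 11 to 54 in the others. The second component (15.5%) held the 3 arrays numbered 2 without Dex at -11.8, -19.7 and -19.1, and the others between -2.48 and 12.9.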

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

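The tests of explanations in this part, and the split by replicate number itself, were chosen after the result was seen, and so were the counts of other splits within the arrays of 1 number; the remaining counts of other splits were planned. The Dex effect differed between the arrays numbered 2 and those numbered 1 in 28 probe sets, by a test of the difference itself. The pattern behind it was that the 16 measured glucocorticoid receptor targets lay at or near the level of the Dex arrays in the 3 arrays numbered 1 and labelled without Dex. Their mean log2 level, centred over the 12 arrays, was 0.167, 0.199 and 0.019 in unstimulated 1, IL-9 1 and CCL1 1, and -0.413, -0.319 and -0.481 in unstimulated 2, IL-9 2 and CCL1 2. The 6 Dex arrays lay between 0.0278 and 0.281. The difference between Dex and no Dex was 0.276 over all 12 arrays (exact two-sided permutation p = 0.0758). It was -0.0218 in the arrays numbered 1 and 0.574 in those numbered 2, where 3 against 3 arrays cannot give p below 0.1.

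For this pattern, a technical difference that shifts the list alike in every array of a number is argued against. The median number 1 minus number 2 difference of the list was 0.63 without Dex and -0.070 with Dex. By camera the difference between these values passed at the preset correlation (adjusted p = 6.19e-09) and at an estimated one (adjusted p = 0.045). At an estimated correlation it was lost whichever array was left out (adjusted p = 0.0662 to 0.311). The same arrays define the pattern, so this test is not independent of it. Exchanged labels between Dex and no-Dex arrays of this series are argued against too, because no Dex array lay low: the lowest Dex array was 0.347 above the highest array numbered 2 without Dex. A glucocorticoid present in the 3 cultures, for example from serum or from Dex itself, or RNA of Dex-treated cells under their labels, stays open. The 16 genes raised by Dex in the arrays numbered 2 alone had a median Dex difference of -0.0495 in the arrays numbered 1, which restates the pattern and favours neither reading. A change of the cells between the numbers stays open too and was not tested.

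Dusp6 had a signal of 716 in the array CCL1 2, which was left out of the 11 comparisons, against 204 and 175 in the unstimulated arrays. It was picked out because a signal above the controls appeared in an array outside these comparisons. With that array added, the CCL1 versus unstimulated difference of Dusp6 was 1.69 (adjusted p = 0.00260 by limma, with 0.00260 to 0.262 over the other settings), and no explanation was tested.

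The number of other splits of the same arrays with as many probe sets was counted in fits of 2 groups. For IL-9 averaged over Dex conditions the real split gave 20 and the highest other 2. Only 1 of 35 splits, the real one, gave as many, which is the smallest share that 35 splits can give. For CCL1 the real split gave 4 and the highest other 3 (1 of 35), and for IL-9 against CCL1 107 and 25 (1 of 35). A margin of 1 probe set does not exclude chance for CCL1. For IL-9 and for IL-9 against CCL1 every other split gave a far lower count. These shares were not adjusted for the number of comparisons. The highest other splits for IL-9 and for CCL1 were those by replicate number, for which these fits held no term. For Dex averaged over cytokine conditions the real split gave 0, which every split equals or exceeds (100 of 100), so this count says nothing about chance. The highest other split gave 63 and set the 4 arrays with IL-9 and unstimulated 2 against the others, which is the split by IL-9 with 1 further array. With 10 splits no share under 0.05 can be reached: for Dex in the arrays numbered 1 the real count was 0 and the highest other 0 (10 of 10 splits as large), and in those numbered 2, with 12 arrays available, 17 and 2 (1 of 10).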

How the results depend on the processing

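The split by replicate number, the arrays of 1 number alone, every setting of the number results and the list tests with 1 array left out were added after the data were seen; the other settings were planned. Of 362 comparisons of called named genes under planned settings other than leaving out an array, 339 kept direction and call, 23 kept direction without the call and 0 reversed; of 387 with 1 array left out, 296 kept the call and 0 reversed. Of 24 list shifts, 7 held with an estimated correlation and 15 with fry. With 1 array left out, 222 of 254 list tests at the preset correlation outside the averages with Dex split by number kept the call, 32 kept direction without it and 0 reversed. With a pseudocount of 1, IL-9 versus CCL1 gave 19 probe sets; with 64, Dex plus IL-9 versus Dex gave 5 and CCL1 versus unstimulated 1. Without a filter, IL-9 versus CCL1 gave 18 and Dex in the arrays numbered 2 44, with more probe sets tested. Median centring gave 5 for Dex plus IL-9 versus Dex, and no intensity trend gave 0 for Dex plus CCL1 versus Dex. The use of 1 probe set per gene gave 1 for CCL1 versus unstimulated. A log2 change of at least 1 left 21 for IL-9 versus CCL1 and 39 for Dex in the arrays numbered 2, by its construction. The array CCL1 2 added gave 1 for CCL1 versus unstimulated, 5 for Dex plus IL-9 versus Dex and 3 for CCL1 averaged. With Dex split by number, IL-9 averaged gave 111, CCL1 averaged 44 and IL-9 versus CCL1 105, and with CCL1 2 added 142, 110 and 159. The arrays numbered 1 alone gave 210, 108 and 165, and those numbered 2 alone 2, 0 and 9, with 23 for Dex averaged. Apart from the filter and the size limit, the cause was not tested. Median centring moved the median of all probe sets from -0.0306 to 0.0755 in CCL1 versus unstimulated and from 0.0206 to -0.123 in the CCL1 interaction. Same-numbered deviations correlated above 0.1 in 10 of 15 pairs of groups (r from -0.00626 to 0.349). Because this did not hold for every pair and the labels do not say what the numbers mark, the arrays were not treated as paired, though they differed by number, with 108 probe sets called between the numbers without Dex and 3 with Dex. With the replicate block, Dex plus IL-9 versus Dex gave 6 probe sets, and no other count moved by over 1.5 times. Among the named genes Ndrg3 passed there (adjusted p = 0.0106) and Zfp36 and Pglyrp2 did not in IL-9 versus CCL1. With 1 array left out, counts ranged from 0 to 529 for Dex versus unstimulated, 3 to 5 for IL-9 versus unstimulated, 0 to 1 for CCL1 versus unstimulated, 2 to 668 for Dex plus IL-9 versus Dex, 0 to 528 for Dex plus CCL1 versus Dex, 0 to 271 and 0 to 101 for the IL-9 and CCL1 interactions. They ranged from 5 to 358 for IL-9 averaged, 1 to 66 for CCL1 averaged, 14 to 52 for IL-9 versus CCL1, 29 to 117 for Dex in the arrays numbered 2 and 15 to 44 for the difference between numbers; Dex averaged and Dex in the arrays numbered 1 stayed at 0. Without Dex replicate 1 the array Dex 2 stood alone in its group and was assumed to vary like the others. Without the tested CCL1 array its contrasts had no value. Signals near the filter, 6.32, lie close to background and their changes are understated.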

Other observations

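The list tests of IL-9 and CCL1 in this part were chosen after the results were seen, and so were the 3 genes of T cell regulation whose signals come first. Ccr8, the receptor of CCL1, had signals of 159, 86.9 and 243 in unstimulated 2, IL-9 2 and CCL1 2 and of 456, 271 and 623 in Dex 2, Dex+IL-9 2 and Dex+CCL1 2. Tnfsf14, a costimulatory ligand, had 11.8, 18.6 and 11.9 without Dex and 91.8, 106 and 22.9 with Dex in the same order. Bcl2l11 had 153, 95.5 and 134 against 673, 333 and 297. In the arrays numbered 1, in the same order, Ccr8 had 405, 306 and 590 without Dex and 400, 298 and 553 with Dex. Tnfsf14 had 79.5, 87.7 and 34.9 against 81.4, 90.5 and 30.9 there, and Bcl2l11 420, 330 and 338 against 374, 269 and 264.

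The hypothesis that IL-9 lowers the genes that Dex raises was put forward after these values were seen and tested in the arrays numbered 1. Apart from the filter and the choice of probe set, which used all 12 arrays, those arrays had no part in choosing the genes. The values that prompted the hypothesis include their signals for Ccr8 and Bcl2l11, both among the 16 genes. The test is therefore not independent of them. The 16 genes raised by Dex in the arrays numbered 2 had a median IL-9 change of -0.27 in the arrays numbered 1, with 12 below 0. It lay below that of all 10000 random lists of the same size and matched level (percentile 0). Random lists leave out the correlation between these genes, estimated at 0.118, so this rank overstates the evidence. The list test gave p = 0.000840 with a preset correlation and p = 0.164 with an estimated one, so the test leaves open whether IL-9 may lower these genes as a set. For CCL1 the median was 0.023, with 7 below 0 (p = 0.748 with an estimated correlation); genes that lie on both sides of 0 leave the same hypothesis open for CCL1.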
